A study of Mus musculus with 13 samples.

How the data were processed

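Messenger RNA levels were measured on 13 one-colour Affymetrix arrays with a biotin label: 3 tumours and 2 control livers at 11 months, and 5 tumours and 3 control livers at 14 months. Per the labels' protocols, RNA was taken from frozen liver with Super RNApure and 6 ug of total RNA was turned into labelled cRNA by the standard Affymetrix procedure. The authors' values are on a log2 scale, made by robust multi-array analysis (RMA) in the Genomics Suite software of Partek, per the submitters' processing notes. The version of that software, its background settings and whether all arrays were processed in 1 run are not given in the sources used here. The log base was taken from the values: array medians lie between 5.127 and 5.218, the lowest values between 1.935 and 2.147 and the highest between 14.581 and 14.839. Groups and ages come from the labels. Replicate numbers follow the order of the samples and carry no pairing.

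The table holds 45101 probe sets with 0 missing values. Of these, 64 are array controls, 34945 name 1 gene, 932 name several and 9160 name none. Each of 18193 genes was represented by the probe set with the highest mean level over all arrays, and no filter on level was used. Probe sets with several genes or none were tested apart. No coordinates are printed, since no genome build is named for the values.

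All arrays entered 1 fit with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes, prior degrees of freedom 2.314). The comparisons were tumours against controls with the 2 ages weighted equally, the same at 11 and at 14 months, the difference between these, tumours at 14 against 11 months, and controls at 14 against 11 months. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Fold changes with the ages combined weigh the ages equally and so can differ from the difference of the printed means over 8 tumours and 5 controls. Sizes of folds, rises and falls are log2 fold changes, except where 2-fold is written. The 40 gene lists were written before the data were examined, and each was tested with camera at a preset correlation of 0.01, with p-values adjusted over the lists. Counts in lists are given over all genes, and again with p-values adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

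The comparisons, tests, lists, threshold and the rule for naming genes were fixed before the data were examined. With the ages combined the rule takes the 12 largest rises and 12 largest falls among genes past the threshold whose tumours all lie on one side of all controls. It adds from each list the 3 largest changes past the threshold and the largest one in the opposite direction, all measured genes of the 2 miR-122 lists, up to 5 genes in each direction of every other comparison, or the 3 with the smallest p if none passed, and a set of marker genes. This gave 170 genes. The examples printed were drawn from them, with preference for genes whose call held when each array was left out. Of these genes 147 passed with the ages combined and 78 passed with each array left out in turn. In all of the 23 settings below in which single genes were followed, 62 passed. Left out of these 23 were all probe sets, only genes above the median level, no age term and only the arrays compared. An adjusted p under 0.01 and a change of at least 2-fold were also left out.

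Also fixed before the data were examined were these alternatives: all probe sets, the mean of a gene's probe sets, quantile normalisation repeated, arrays shifted to 1 median, eBayes with a trend and robust spread, array weights, KO_tumor_14M replicates 1 and 2 averaged, each array left out in turn, an adjusted p under 0.01, a change of at least 2-fold, only the arrays of the 2 groups compared, only genes above the median level, no age term, camera with an estimated correlation, and fry. After the data were seen 4 more were added: without both nearly identical controls, without control_liver_14M replicate 3 and with KO_tumor_14M replicates 1 and 2 averaged, only arrays whose titles carry a number, and the arrays without a number as a block.

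The fit was tested on simulated data with 50 genes shifted at each of 4 sizes. With the ages combined it found 40% of genes shifted by 0.5 on the log2 scale, 78% at 1, 92% at 1.5 and 96% at 2, with 9 false calls among 162. At 11 months these were 6%, 50%, 70% and 94% (7 false of 117), and at 14 months 20%, 66%, 88% and 92% (3 false of 136). The simulated noise was independent between genes and had the same spread for a gene in all groups. These rates may not hold where tumours vary more than controls or genes move together. The number of arrays, 2 to 5 per group, limits the precision.

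An analysis of miR-122 seed matches had been planned for the case that transcripts with 3 prime untranslated regions were given, and was not run. Background correction, scan date and slide could not be tested with the values used here.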

Results

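Gene expression was measured on 13 one-colour Affymetrix arrays, with 1 RNA sample on each. There were 8 liver tumours of mice lacking mir-122, a microRNA abundant in liver, and 5 livers of control mice. At 11 months there were 3 tumours and 2 control livers, and at 14 months 5 tumours and 3 control livers. No liver without a tumour from a knockout mouse was measured, so the effect of the genotype and that of the tumour cannot be separated. No probe set for the miR-122 locus is among the genes, so the deleted transcript was not measured here and the genotype labels were not checked by it. Nothing in the labels says that the tumours came from separate mice. The design text speaks of 2 and 3 control mice but of 3 and 5 tumours of knockout mice, and the titles of 10 arrays carry different numbers whose meaning is not stated. The p-values below therefore measure the spread between these samples.

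The first principal component held 49.5% of the variance over all probe sets and the second 12.8%. On the first, the 5 controls lay between -79.4 and -64.5. Of the 8 tumours, 5 lay between 67.8 and 92.2, while KO_tumor_11M replicate 1 lay at -2.74, KO_tumor_11M replicate 2 at -17.8 and KO_tumor_14M replicate 4 at 1.55. On the second component these 3 tumours lay at -72.4, -25.2 and -72.2 in the same order, and the other arrays at 7.93 or above. Dbp, a clock output gene looked at after the arrays had been seen, was at 9.31, 9.41 and 8.89 in these 3 tumours, at 8.47 in KO_tumor_14M replicate 5 and at 5.44 to 6.03 in the other 4, and its counterpart Arntl at 6.71, 5.89 and 6.73, at 7.06, and at 8.30 to 8.52. In controls Dbp was at 8.98 to 11.16, except for 5.66 in control_liver_14M replicate 1. Among the controls, control_liver_11M replicate 1 and control_liver_14M replicate 3 correlated at r = 0.995, against at most 0.991 for the other 9 pairs. Only 63 probe sets differed over 2-fold between them, against 485 to 1315 for the other pairs of controls.

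**Figure D1:**
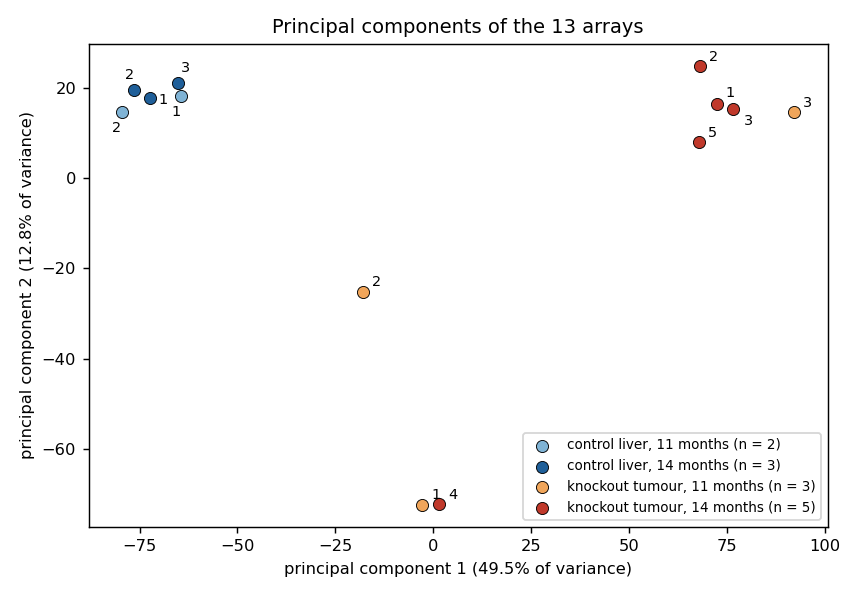
Principal components of the 13 arrays over all probe sets. Numbers are the replicate numbers within each group.

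Igf2, a fetal growth factor, had a log2 level of 12.62 ± 0.64 in tumours (mean ± SD, n = 8) and 6.25 ± 0.66 in controls (n = 5), a log2 fold change of 6.41 (adjusted p = 1.9e-06). Afp, the fetal serum albumin, stood at 11.27 ± 1.37 against 5.52 ± 0.56 (5.57, adjusted p = 0.000148), and Lcn2, an iron-siderophore carrier, at 13.03 ± 0.49 against 7.79 ± 1.95 (5.31, adjusted p = 0.000812). Lcn2 was at 9.73 and 9.98 in the nearly identical controls and at 5.88 to 7.22 in the other 3. Its log2 fold change was 6.83 without that pair (adjusted p = 4.06e-05) and 4.35 without control_liver_11M replicate 2. It passed the threshold in all 23 settings in which single genes were followed. The surface protein Ly6d rose by 4.94, the transcription factor Sox4 by 4.72, the lysosomal GTPase Rragd by 4.71, the desaturase Scd2 by 4.68, the ubiquitin-like Ubd by 4.55 and the progenitor marker Prom1 by 4.53. Cdc42ep5, Elapor1 and Esm1 rose by 4.85, 4.65 and 4.43. The largest falls were those of Hsd3b5, a steroid dehydrogenase (3.86 ± 0.95 against 11.75 ± 0.44, log2 fold change -7.90, adjusted p = 6.4e-06), and Slco1a1, an organic anion carrier (5.31 ± 0.57 against 11.81 ± 0.32, -6.48, adjusted p = 1.11e-06). The sulfotransferase Sult2a8 (-6.07), the major urinary protein Mup10 (-5.83), the fatty acid elongase Elovl3 (-5.60), Fam47e (-4.78) and the haemoglobin scavenger receptor Cd163 (-4.07) also fell. With the mean of a gene's probe sets the log2 fold changes were smaller, at 3.55 for Afp, 2.37 for Rragd, 2.33 for Cdc42ep5 and 1.84 for Sox4, all past the threshold. Sult2a8 was lost without both nearly identical controls or with only the arrays whose titles carry a number (adjusted p = 0.0654 and 0.0627). Albumin itself, Alb, was at 14.64 ± 0.11 in tumours and 14.65 ± 0.01 in controls. These values lie near the highest of the arrays (14.581 to 14.839), so a change in Alb may not be seen. Probe sets of multigene families such as Mup and Cyp2c can pick up their close relatives.

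**Figure D2:**
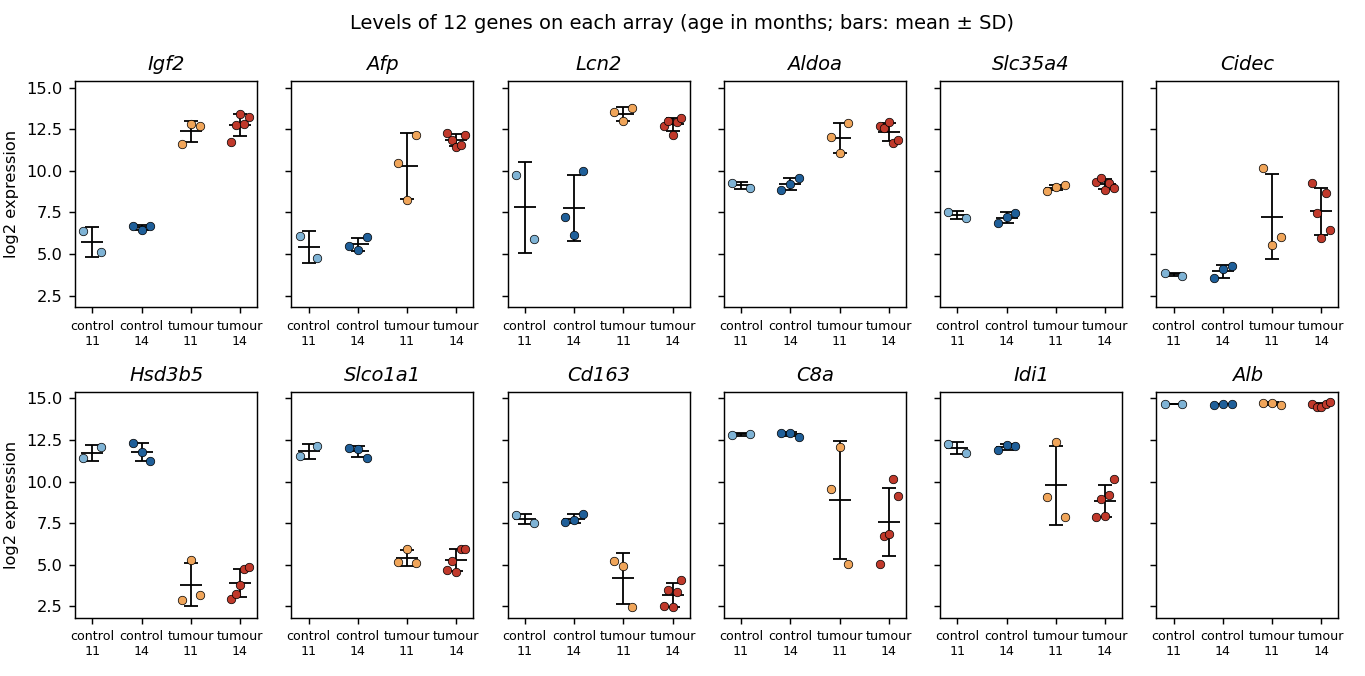
Log2 levels of 12 genes on each array. Bars give the mean and SD of each group.

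With the ages combined, limma called 3657 of 18193 genes at an adjusted p under 0.05, 1872 higher and 1785 lower in tumours. Of these, 849 rose and 375 fell by at least 2-fold. Across all genes the median log2 fold change was -0.05. Quantile normalisation repeated on the values gave 1705 higher and 2129 lower, 44.5% higher against 51.2%. Of 100 splits of the arrays drawn within each age, 1, the real one, called as many genes, and the highest other called 255. The 11-month control group has 2 arrays and carries much of the weight: counted as tumour vs control, ages combined: genes past the threshold numbered 1963 without control_liver_11M replicate 1 and 1814 without replicate 2. Without both nearly identical controls the count was 1368, and with only the arrays whose titles carry a number it was 1759. Of the 147 genes named by rule that passed, these settings lost 78 and 69. In all of the 23 settings in which single genes were followed, 62 passed.

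Of 35 measured published targets of miR-122, 22 were higher, 0 lower and 13 not past the threshold (22 higher and 0 lower when adjusted over the list alone). Aldoa, an aldolase, was at 12.21 ± 0.66 in tumours (n = 8) and 9.18 ± 0.28 in controls (n = 5, adjusted p = 0.000216). Slc35a4, a nucleotide sugar carrier, was at 9.12 ± 0.26 against 7.25 ± 0.27 (log2 fold change 1.83, adjusted p = 5.58e-05), Fundc2 at 8.64 ± 0.39 against 6.51 ± 0.16 (2.10, adjusted p = 3.19e-05) and Bckdk, a kinase of branched-chain amino acid breakdown, at 8.41 ± 0.21 against 7.35 ± 0.18 (1.10, adjusted p = 0.000159). Pkm (2.48), Rell1 (2.07), Tmed3 (1.69), Iqgap1 (1.57), Ccng1 (1.56), P4ha1 (1.53) and Ndrg3 (1.52) also rose. With the mean of a gene's probe sets some log2 fold changes were smaller, still past the threshold: 0.84 for Slc35a4, 1.23 for Fundc2, 0.71 for Iqgap1 and 0.95 for Tmed3. Pkm was lost without both nearly identical controls (adjusted p = 0.0633). Igf1r (0.13), Srf (-0.24), Cux1 (-0.02) and Foxp1 (0.09) were not past the threshold. The median log2 fold change of the list was 1.09 (camera adjusted p = 1.01e-12, and adjusted p = 0.00306 with an estimated correlation). A second list of 8 genes was drawn from what the knockout study itself named, so it is not independent evidence. In it 6 were higher and 0 lower (6 and 0 over the list alone), with a median of 1.14 (adjusted p = 0.000101, and adjusted p = 0.0389 with an estimated correlation).

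In that second list the lipid droplet protein Cidec rose by 3.54 (adjusted p = 0.0117), Vim by 2.06, Ccl2 by 1.64, Tgfb1 by 1.05, Mapre1 by 0.87 and Agpat1 by 0.59. The zinc finger factor Klf6 (1.23, adjusted p = 0.144) and Mttp, which loads lipid onto apolipoprotein B (-0.19, adjusted p = 0.667), were not past the threshold. With the mean of a gene's probe sets Tgfb1 stood at 0.49 and Mapre1 at 0.56. Cidec was lost without control_liver_11M replicate 2 (adjusted p = 0.0516), and Cidec, Ccl2 and Mapre1 without both nearly identical controls (adjusted p from 0.0746 to 0.107). With only the arrays whose titles carry a number Cidec (adjusted p = 0.0628) and Ccl2 (adjusted p = 0.083) were lost, and Ccl2 also without control_liver_14M replicate 3 and with KO_tumor_14M replicates 1 and 2 averaged (adjusted p = 0.0645). Ccl2 was lost without any 1 of the 5 controls, KO_tumor_11M replicate 3 or KO_tumor_14M replicate 5 (adjusted p from 0.0513 to 0.12), and Klf6 passed without control_liver_14M replicate 3 (adjusted p = 0.0242). Klf6 was at 8.89 and 8.88 in the nearly identical controls, at 5.89 to 6.29 in the other 3 controls and at 7.72 to 9.08 in tumours. Without the nearly identical pair its log2 fold change was 2.37 (adjusted p = 0.0033), so its call rests on these arrays.

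Of 20 measured genes of cholesterol synthesis, 0 were higher and 12 lower (18 lower over the list alone), with a median of -1.40. Idi1, an isomerase of the mevalonate pathway, was at 9.17 ± 1.53 in tumours (n = 8) and 12.04 ± 0.22 in controls (n = 5), a log2 fold change of -2.74 (adjusted p = 0.0167), and the sterol enzymes Msmo1 and Tm7sf2 fell by 2.41 and 2.36. In KO_tumor_11M replicate 2 Idi1 was at 12.40 (controls 11.74 to 12.27) and Msmo1 at 12.41 (controls 11.78 to 12.49), so this tumour showed no fall of either. In contrast, 6 of 20 genes of lipid droplets and lipid uptake were higher and 0 lower (6 and 0 over the list alone, median 1.05), led by the fatty acid binding protein Fabp4 (10.71 ± 1.29 against 6.52 ± 0.46, 4.13, adjusted p = 0.0014) and the lipase Lpl (11.98 ± 0.53 against 8.96 ± 0.67, 2.96, adjusted p = 0.000188). The lowest log2 fold change of Fabp4 over the settings was 2.75, still past the threshold. Camera gave an adjusted p of 3.95e-07 for cholesterol synthesis and 0.000223 for lipid droplets. With an estimated correlation each list had an adjusted p = 0.387. The lists of lipoprotein secretion (2 higher and 3 lower of 19, adjusted p = 0.172), fatty acid synthesis (2 and 2 of 21, adjusted p = 0.59) and fatty acid oxidation (0 and 3 of 22, adjusted p = 0.126) did not pass. Over these lists alone the counts were 2 and 3, 2 and 2, and 0 and 1. In them Apoc2 rose by 1.21 and Scd2 by 4.68, while Acss2 fell by 1.89. Without control_liver_11M replicate 1, Idi1 (adjusted p = 0.0708) and Msmo1 (adjusted p = 0.0677) were lost, and without replicate 2 Idi1 (adjusted p = 0.0533) and Tm7sf2 (adjusted p = 0.0535). All 3 were lost without both nearly identical controls or with only the arrays whose titles carry a number (adjusted p from 0.0699 to 0.118).

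Lists of hepatocyte functions held mostly falls among the genes that passed, with Alb (0.00, adjusted p = 0.987) and the transcription factor Hnf4a (-0.12, adjusted p = 0.547) not past the threshold. The level of Alb lay near the top of the scale on every array, so a change in it may not be seen. Complement and coagulation had 0 higher and 13 lower of 29 (20 lower over the list alone, median -0.69): C8b was at 8.15 ± 1.61 in tumours (n = 8) and 11.39 ± 0.09 in controls (n = 5), a log2 fold change of -3.14 (adjusted p = 0.0113), and C8a also fell. Bile acid genes had 1 higher and 12 lower of 27 (1 and 13 over the list alone, median -1.24), with the exporter Abcc4 higher (9.17 ± 1.46 against 5.82 ± 0.20, 3.12, adjusted p = 0.00366). Cytochrome P450 genes had 0 higher and 6 lower of 27 (7 over the list alone, median -1.25), Cyp2c37 falling by 4.41. Hepatocyte identity genes had 0 higher and 5 lower of 25 (6 over the list alone, median -0.26), such as the asialoglycoprotein receptor gene Asgr2 (-1.53) and Fetub (-1.39). KO_tumor_11M replicate 2 stood at or near the controls, with Asgr2 at 9.78 (controls 9.15 to 9.68), Fetub at 12.14 (12.08 to 12.30) and C8b at 11.21 (11.27 to 11.51). Camera gave adjusted p = 9.58e-08, 0.000457, 0.000861 and 0.025 for these 4 lists in turn, and adjusted p = 0.316, 0.402, 0.495 and 0.387 with an estimated correlation. With fry the P450 list was lost (adjusted p = 0.0702). C8a, C8b, Cyp2c37, Asgr2 and Fetub were lost without both nearly identical controls or with only the arrays whose titles carry a number (adjusted p from 0.0727 to 0.125). Without control_liver_11M replicate 1 or 2 the calls of C8a, Cyp2c37, Asgr2 and Fetub were lost (adjusted p from 0.0604 to 0.0917). Cyp2c37 and Asgr2 were also lost without control_liver_14M replicate 2 (adjusted p = 0.0541 and 0.0531). The hepatocyte identity list was lost without control_liver_11M replicate 2 (adjusted p = 0.0677).

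Of 13 gluconeogenesis genes 0 were higher and 6 lower (7 lower over the list alone, median -0.74), with the glycogen-targeting subunit Ppp1r3b at 8.33 ± 0.78 in tumours (n = 8) and 10.53 ± 0.31 in controls (n = 5), a log2 fold change of -2.21 (adjusted p = 0.003). Of 15 glycolysis genes 7 were higher and 0 lower (7 and 0 over the list alone, median 0.53), Aldoa and Pkm among them. Pericentral genes had 2 higher and 6 lower of 20 (3 and 11 over the list alone, median -0.89), the Wnt feedback ligase Rnf43 falling by 2.37 (4.29 ± 0.62 against 6.67 ± 0.30, adjusted p = 0.000356). Camera gave adjusted p = 0.025, 4.68e-05 and 0.0057 for these lists, and adjusted p = 0.439, 0.387 and 0.444 with an estimated correlation. Periportal genes (1 higher and 3 lower of 15, the same over the list alone, adjusted p = 0.193) and urea and amino acid genes (0 and 3 of 23, the same over the list alone, adjusted p = 0.508) did not pass, although the urea cycle enzyme Otc fell by 1.96 (lost without both nearly identical controls or with only the arrays whose titles carry a number, adjusted p = 0.0633 and 0.0619). The gluconeogenesis list was lost without control_liver_11M replicate 2 (adjusted p = 0.0796) or KO_tumor_14M replicate 4 (adjusted p = 0.0718).

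Of 16 measured genes known to be higher in male than in female mouse liver, 0 were higher and 13 lower in tumours (15 lower over the list alone), with a median log2 fold change of -2.88. Hsd3b5 and Slco1a1 belong to this group, as does Elovl3 (5.24 ± 1.42 in tumours, n = 8, against 10.85 ± 1.62 in controls, n = 5, -5.60, adjusted p = 0.00183). Camera gave an adjusted p = 2.02e-11, and adjusted p = 0.102 with an estimated correlation. Of 14 genes known to be higher in female liver, 2 were higher and 1 lower (the same over the list alone, median 0.38, adjusted p = 0.125), among them the steroid hydroxylase Cyp17a1 (11.24 ± 1.58 against 7.52 ± 0.77, 3.68, adjusted p = 0.00613, lost without both nearly identical controls or with only the arrays whose titles carry a number, adjusted p = 0.0627 and 0.0526). Of 4 sex-linked genes 0 were higher and 2 lower (the same over the list alone, adjusted p = 0.193): the Y-linked Eif2s3y (8.64 ± 0.41 against 9.26 ± 0.18, -0.54, adjusted p = 0.0337) and Xist, which silences the second X chromosome (4.68 ± 0.18 against 5.03 ± 0.11, -0.36, adjusted p = 0.0234). Xist was lost without control_liver_11M replicate 1 or 2, control_liver_14M replicate 2 or KO_tumor_11M replicate 3 (adjusted p from 0.0522 to 0.0975), and Eif2s3y without these, control_liver_14M replicate 3 or KO_tumor_14M replicate 2 (adjusted p from 0.0524 to 0.139). With the mean of a gene's probe sets neither passed (Eif2s3y -0.23, adjusted p = 0.137, and Xist -0.17, adjusted p = 0.0745). Xist lay at 4.463 to 5.199 over all arrays, against a median level of all probe sets of 5.196. It was not shown to be above background.

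Of 30 measured markers of fetal liver and of liver tumours, 16 were higher and 0 lower (19 higher over the list alone, median 1.78), including Igf2, Afp, Lcn2 and Prom1, while Gpc3, a glypican used as a marker of human liver cancer, was not past the threshold (-0.03, adjusted p = 0.906). Gpc3 was at 4.14 to 5.03 on all arrays, below the median level of all probe sets (5.196), so it was not shown to be above background. Of 19 imprinted genes 11 were higher and 0 lower (12 higher over the list alone, median 1.03). Camera gave adjusted p = 1.68e-11 and 2.41e-05 for these lists, and adjusted p = 0.0931 with an estimated correlation for each. Of 49 cell cycle genes 4 were higher and 0 lower (0 over the list alone, median 1.01, adjusted p = 1.63e-07, and adjusted p = 0.444 with an estimated correlation), and with fry the list was lost (adjusted p = 0.0935). The proliferation marker Mki67 was at 7.25 ± 1.45 in tumours (n = 8) and 4.99 ± 0.62 in controls (n = 5), a log2 fold change of 2.07 (adjusted p = 0.0364). KO_tumor_11M replicate 1 lay within the controls, with Mki67 at 4.61 (controls 4.35 to 5.73), and both it and KO_tumor_11M replicate 2 did for Rrm2 (7.08 and 7.28, controls 6.17 to 7.70) and Ttk (3.69 and 3.91, controls 3.27 to 4.68). Mki67 was lost without control_liver_11M replicate 1 or 2, control_liver_14M replicate 1 or 2, or KO_tumor_14M replicate 2 or 5 (adjusted p from 0.0528 to 0.132), and in 3 further settings: without both nearly identical controls (adjusted p = 0.0864), with only the arrays whose titles carry a number (adjusted p = 0.0865), and without control_liver_14M replicate 3 and with KO_tumor_14M replicates 1 and 2 averaged (adjusted p = 0.0566). Targets of p53 had 6 higher and 0 lower of 21 (6 and 0 over the list alone, median 0.46, adjusted p = 0.0032, and adjusted p = 0.387 with an estimated correlation), with the cell cycle inhibitor Cdkn1a rising by 2.07 (adjusted p = 0.00563).

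Among stress and metal genes, NRF2 targets and glutathione enzymes had 6 higher and 1 lower of 27 (6 and 1 over the list alone, median 0.16, adjusted p = 0.0222, and adjusted p = 0.495 with an estimated correlation). The carbonyl reductase Cbr3 was at 10.67 ± 1.52 in tumours (n = 8) and 6.23 ± 0.86 in controls (n = 5), a log2 fold change of 4.21 (adjusted p = 0.00201). The list was lost when only genes above the median level were kept (adjusted p = 0.134), with fry (adjusted p = 0.178), and without control_liver_11M replicate 2, control_liver_14M replicate 1 or KO_tumor_14M replicate 4 (adjusted p = 0.0972, 0.0533 and 0.111). Iron genes had 4 higher and 1 lower of 18 (5 and 1 over the list alone, adjusted p = 0.356), with the hepcidin regulator Hjv among those higher. Of 23 genes of the unfolded protein response 1 was higher and 0 lower (0 over the list alone, adjusted p = 0.652).

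Extracellular matrix genes had 17 higher and 0 lower of 36 (20 higher over the list alone, median 1.10). Col1a1, a chain of type I collagen, was at 8.54 ± 1.63 in tumours (n = 8) and 5.41 ± 0.55 in controls (n = 5), a log2 fold change of 3.14 (adjusted p = 0.0167), and the collagenase Mmp13 rose by 2.80 (adjusted p = 0.00985). Interferon-stimulated genes had 19 higher and 1 lower of 29 (21 and 1 over the list alone, median 1.83), such as Ifit2 (3.66, adjusted p = 0.00319) and the chemokine Cxcl10 (3.46). KO_tumor_11M replicate 1 and KO_tumor_14M replicate 4 stood apart, with Cxcl10 at 8.18 and 7.89 (controls 4.71 to 8.19, other tumours 10.01 to 10.93) and Ifit2 at 6.45 and 6.88 (other tumours 8.84 to 10.26). In the nearly identical controls Cxcl10 was at 7.777 and 8.189, and in the other controls at 4.71 to 5.655. The log2 fold change of Cxcl10 went from 2.83 to 4.585 over the settings. Genes of inflammation had 8 higher and 3 lower of 33 (11 and 3 over the list alone, median 0.57), among them the NF-kappaB inhibitor Tnfaip3 (2.13). Camera gave adjusted p = 5.21e-11, 9.79e-10 and 0.000387 for these 3 lists, and adjusted p = 0.387 with an estimated correlation for each. Acute phase genes had 4 higher and 1 lower of 24 (4 and 3 over the list alone); their median was -0.05, while their mean was 0.23 and the direction of the test up (adjusted p = 0.596). In that list Lcn2 rose and Apcs fell by 1.65. Without control_liver_11M replicate 2 the calls of Col1a1 (adjusted p = 0.0756) and Cxcl10 (adjusted p = 0.0614) were lost, and without both nearly identical controls those of Col1a1, Mmp13 and Apcs (adjusted p from 0.0664 to 0.086). With only the arrays whose titles carry a number Tnfaip3 (adjusted p = 0.051) and Mmp13 (adjusted p = 0.0647) were lost.

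Markers of macrophages had 16 higher and 1 lower of 28 (18 and 3 over the list alone, median 1.31, adjusted p = 2.17e-05, and adjusted p = 0.387 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 was at 11.41 ± 1.03 in tumours (n = 8) and 7.15 ± 1.02 in controls (n = 5), a log2 fold change of 4.31 (adjusted p = 0.000938), and Ms4a7 rose by 3.55 (2.07 with the mean of its probe sets). Cd163, which marks resident Kupffer cells, fell, and Adgre1 was not past the threshold (0.91, adjusted p = 0.0588), although it passed without KO_tumor_11M replicate 1 or KO_tumor_14M replicate 4 or 5 (adjusted p = 0.0164, 0.0443 and 0.0447). Neutrophil markers had 6 higher and 0 lower of 17 (9 higher over the list alone, median 0.53, adjusted p = 0.00175, and adjusted p = 0.387 with an estimated correlation), including S100a9 (8.44 ± 0.94 against 5.96 ± 0.71, 2.72, adjusted p = 0.00101) and S100a8 (2.66). Bile duct cell markers had 3 higher and 0 lower of 17 (4 higher over the list alone, median 0.14, adjusted p = 0.0222, and adjusted p = 0.439 with an estimated correlation), the RNA-binding Bicc1 (2.51) and the transcription factor Elf3 (2.04) among them, with the keratin Krt19 not past the threshold (0.06, adjusted p = 0.924). The bile duct list was lost when only genes above the median level were kept (adjusted p = 0.187), and without KO_tumor_11M replicate 2 or KO_tumor_14M replicate 4 (adjusted p = 0.103 and 0.082).

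The remaining cell types did not pass the list test. T cell markers had 0 higher and 0 lower of 18 (0 over the list alone, adjusted p = 0.0914), with Cd3e at 0.14 (adjusted p = 0.297). Natural killer cell markers had 2 higher and 1 lower of 15 (adjusted p = 0.151), the lectin-like receptor Klrd1 rising by 1.15, and B cell markers 1 higher and 0 lower of 18 (adjusted p = 0.126), the adaptor Blnk by 1.52. Endothelial markers had 4 higher and 2 lower of 24 (4 and 6 over the list alone, adjusted p = 0.755), with Cd34 at 7.23 ± 1.10 in tumours (n = 8) and 4.77 ± 0.32 in controls (n = 5), a log2 fold change of 2.40 (adjusted p = 0.00843). Stellate cell markers had 2 higher and 5 lower of 20 (adjusted p = 0.808); their median was -0.07 and the test pointed down, while their mean was 0.02. Erythroid genes had 1 higher, the carbonic anhydrase Car2 (3.25), and 1 lower, Klf1 (-1.05), of 12 (adjusted p = 0.745), and their median of -0.07 and mean of 0.07 also differ in sign, with the test down. Genes of adipose tissue, muscle, pancreas and gut had 1 higher, Vil1 (1.85), and 3 lower of 21 (adjusted p = 0.282), with a median of -0.17, a mean of 0.15 and the test down. Without both nearly identical controls Klrd1, Cd34, Car2 and Klf1 were lost (adjusted p from 0.0512 to 0.0838), and with only the arrays whose titles carry a number Klrd1, Cd34 and Car2 (adjusted p from 0.0515 to 0.0567). Over the list alone the counts of the natural killer, B cell, stellate, erythroid and other-tissue lists were the same. Among the splits of the arrays drawn within each age, 18 of 100 gave as many lists past the threshold as the real one, which gave 23 of 40, so the number of lists is no evidence by itself. Only the 2 miR-122 lists passed with an estimated correlation.

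**Figure D3:**
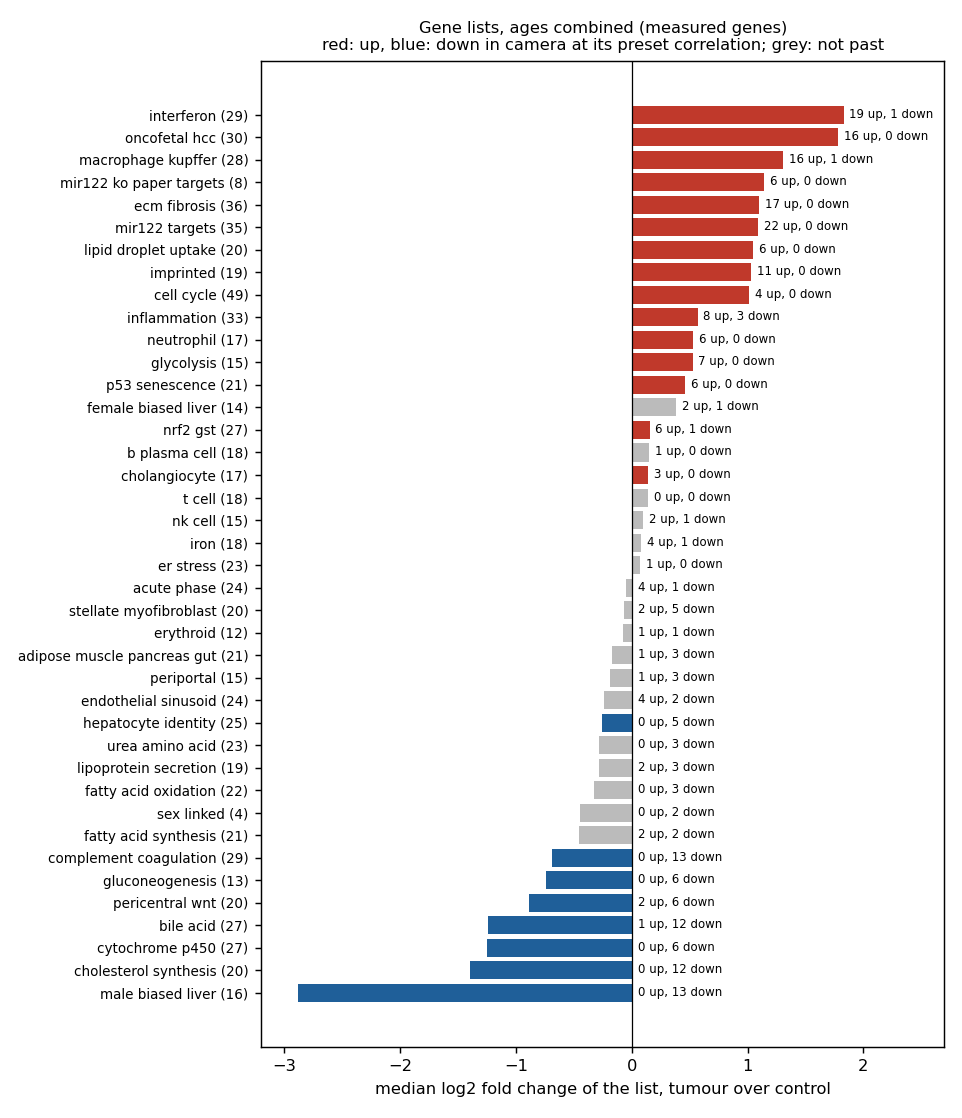
Median log2 fold change of 40 gene lists, tumours against controls with the ages combined. Red and blue mark lists higher and lower by camera at its preset correlation, grey those not past the threshold. Numbers are the members higher and lower.

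At 11 months (3 tumours, 2 controls) Igf2 was higher in tumours by 6.64 (limma adjusted p = 0.000217), and Hsd3b5 and Slco1a1 were lower (-7.95, adjusted p = 0.000594, and -6.41, adjusted p = 0.000121). Lcn2 rose by 5.61 (adjusted p = 0.0321), Afp by 4.86 (adjusted p = 0.022) and Ubd by 4.81 (adjusted p = 0.0176), while Cnmd, a cartilage protein, fell by 3.61 and the actin nucleator Fmn2 by 3.36. In all, 349 genes passed, 238 higher and 111 lower, with 2998 at an unadjusted p under 0.05. Of the miR-122 targets 9 were higher and 0 lower (20 and 0 over the list alone, adjusted p = 1.07e-13, and adjusted p = 0.0023 with an estimated correlation). The oncofetal list had 10 higher and 0 lower (15 and 0 over the list alone, adjusted p = 3.16e-11), the macrophage list 7 and 1 (15 and 1, adjusted p = 1.83e-07) and the male-biased list 0 and 4 (0 and 15, adjusted p = 1.67e-13). For these the values were adjusted p = 0.0842, 0.263 and 0.0786 with an estimated correlation. With control_liver_11M replicate 2 left out, Lcn2, Afp, Ubd, Cnmd and Fmn2 were lost (adjusted p from 0.0772 to 0.285), and with replicate 1 left out Afp, Ubd and Cnmd (adjusted p from 0.0663 to 0.0926). The log2 fold change of Lcn2 was then 3.69 and 7.54. Lcn2 was also lost without control_liver_14M replicate 1, KO_tumor_11M replicate 3 or KO_tumor_14M replicate 2 (adjusted p from 0.0504 to 0.09). Without both nearly identical controls Afp, Ubd and Cnmd were lost (adjusted p from 0.103 to 0.118). With the mean of a gene's probe sets Afp stood at 2.84 and Fmn2 at -2.02, each past the threshold.

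Few arrays stand behind that count. For tumour vs control at 11 months: genes past the threshold numbered 47 and 21 without control_liver_11M replicate 1 or 2, and 171, 165 and 190 without control_liver_14M replicate 1, 2 or 3. They numbered 539, 731 and 88 without KO_tumor_11M replicate 1, 2 or 3, and 220 and 204 without KO_tumor_14M replicate 1 or 2. A fit on the 5 arrays of this age alone called 0 genes, with 2070 at an unadjusted p under 0.05.

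At 14 months (5 tumours, 3 controls) Afp was higher in tumours by 6.28 (limma adjusted p = 0.000534), Igf2 by 6.18 (adjusted p = 3.02e-05), Scd2 by 5.46 (adjusted p = 0.00115) and Sox4 by 5.42 (adjusted p = 0.00118). Hsd3b5 (-7.85, adjusted p = 6.55e-05), Slco1a1 (-6.55, adjusted p = 8.8e-06) and Mup10 (-6.32, adjusted p = 0.00661) were lower. With the mean of its probe sets Sox4 stood at 2.10, and with only the arrays whose titles carry a number Mup10 was lost (adjusted p = 0.084). In all, 2775 genes passed, 1523 higher and 1252 lower, 54.9% higher. Quantile normalisation repeated on the values gave 1226 higher and 1531 lower, 44.5% higher, so which direction holds more genes depends on the scaling. Of 56 splits of these 8 arrays, 1, the real one, called as many, and the highest other called 22. Of the miR-122 targets 20 were higher and 0 lower (22 and 0 over the list alone, adjusted p = 1.58e-11, and adjusted p = 0.00485 with an estimated correlation). The second miR-122 list had 5 higher and 0 lower (5 and 0 over the list alone, adjusted p = 0.000586, and adjusted p = 0.072 with an estimated correlation). Cell cycle genes had 10 higher and 0 lower (31 and 0 over the list alone, adjusted p = 4.6e-10), Mki67 rising by 2.89, and cholesterol synthesis 0 and 12 (0 and 18, adjusted p = 7.96e-08). Their values were adjusted p = 0.43 and 0.415 with an estimated correlation. For tumour vs control at 14 months: genes past the threshold numbered 922, 937 and 1246 without control_liver_14M replicate 1, 2 or 3, and 1843 without KO_tumor_14M replicate 2.

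The tumour effects of the 2 ages correlated over 18193 genes at r = 0.851 (Spearman 0.728). They share no array, but would share a control if the nearly identical arrays were 1 animal, and without both of these r was 0.821. In a test chosen after r was seen, 1 of 560 relabellings within each age, the real one, gave an r as high, the others having a median of -0.0664 and a highest value of 0.801. Of the genes higher at 11 months 219 were also higher at 14 months, where chance would give 19.9, 89 were lower at each age, where chance would give 7.64, and 0 were called in opposite directions. These chance counts take the genes and the 2 comparisons as independent. The effects at 11 months had a slope of 0.72 on those at 14 months. Without KO_tumor_11M replicate 3 the correlation was 0.667.

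**Figure D4:**
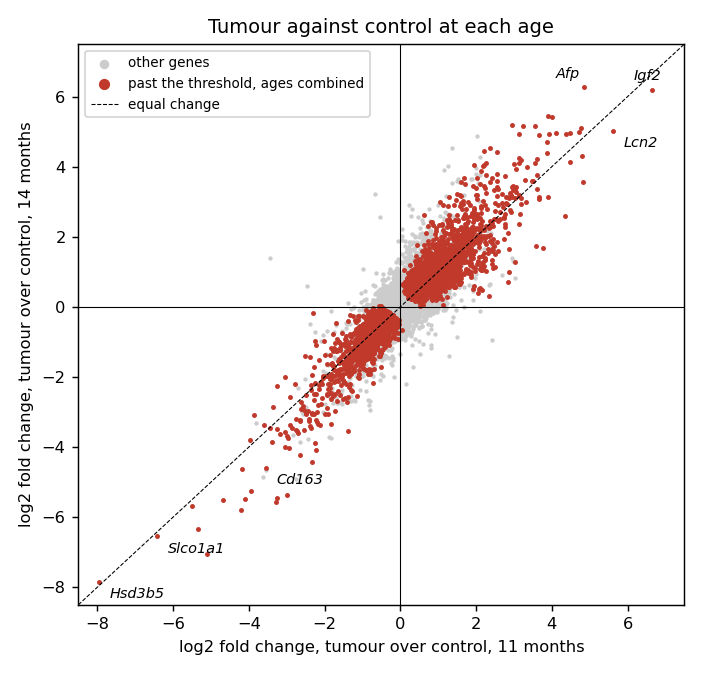
Log2 fold change of each gene, tumours against controls, at 11 and at 14 months. Red marks genes past the threshold with the ages combined, and the dashed line equal change.

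For the difference of the tumour effect between the ages, limma called 0 genes (smallest adjusted p = 0.999), with 544 at an unadjusted p under 0.05. The smallest unadjusted p-values were those of Vac14 (0.62), 1810034E14Rik (0.87) and Tmem267 (2.14). Camera called 10 lists. The tumour effect on cell cycle genes was higher at 14 months (median difference 1.05, adjusted p = 5.57e-07). It was lower for acute phase genes (-0.46, adjusted p = 3.38e-05), neutrophil markers (-0.33, adjusted p = 3.38e-05) and T cell markers (-0.30, adjusted p = 0.000223). For these 3 lists the median log2 fold changes against controls at 14 months were -0.27, 0.33 and 0.02, in the same order. None of the 10 passed otherwise: adjusted p = 0.925 for the cell cycle and adjusted p = 0.83 for the other 3 named lists with an estimated correlation. Without control_liver_11M replicate 1 the count of genes was 1. With 2 to 5 arrays per group, a difference between differences is measured with little precision.

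Between tumours of 14 and 11 months 1 gene passed, Tmem267, a membrane protein, at 6.41 ± 0.52 at 14 months (n = 5) and 3.67 ± 0.16 at 11 months (n = 3), a log2 fold change of 2.74 (limma adjusted p = 0.0377), with 1139 genes at an unadjusted p under 0.05. It was lost with array weights (adjusted p = 0.412), without both nearly identical controls (adjusted p = 0.125), or without control_liver_11M replicate 1 or 2, control_liver_14M replicate 1, any 1 KO_tumor_11M array, or KO_tumor_14M replicate 2, 3, 4 or 5 (adjusted p from 0.0649 to 0.181), and without KO_tumor_11M replicate 1 there were 4 other genes, all lower. Camera placed cell cycle genes higher (median 0.82, adjusted p = 3.47e-09) and acute phase genes lower (-0.43, adjusted p = 9.24e-09) at 14 months, with adjusted p = 0.649 and 0.303 with an estimated correlation. Of 56 splits of the tumours into 3 and 5, 14 called as many genes as the real one. The highest called 2272 and put KO_tumor_11M replicates 1 and 2 and KO_tumor_14M replicate 4 on one side. The first component sets the same tumours apart, so this split is no separate evidence. On the second component they also lie below all other arrays, which are at 7.93 or above. There KO_tumor_11M replicate 1 and KO_tumor_14M replicate 4 (-72.4 and -72.2) lie together and KO_tumor_11M replicate 2 (-25.2) does not. Whether age plays a part in these differences among the tumours stays open.

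Between controls of 14 and 11 months limma called 0 genes (smallest adjusted p = 1), with 326 at an unadjusted p under 0.05. The smallest unadjusted p-values belonged to Vmn1r41 (-0.47), Dmrta1 (0.81) and 4930488B22Rik (0.48). Of the lists, neutrophil markers passed upward (median 0.21, adjusted p = 0.0355, and adjusted p = 0.996 with an estimated correlation), with 0 of 17 genes past the threshold. Without control_liver_11M replicate 1 the count of genes was 1. With 3 and 2 arrays, 2 of which nearly coincide across the ages, small changes with age would not be seen.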

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

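The outlier test and the comparison of lists between ages were fixed before the data were examined, and no further test was chosen here after the result was seen. In each of 170 named genes the 5 arrays of KO_tumor_14M were tested for 1 outlying array by Dixon's ratio, with a critical value of 0.71, which chance passes in about 1 in 20 groups. There were 14 such genes where 8.5 would come by chance. That number takes the genes as independent, while most of the 14 fell on KO_tumor_14M replicate 4, so the excess cannot be interpreted. KO_tumor_14M replicate 4 stood apart in Acss2 (0.841), Pfkp (0.838), Il33 (0.828), Cdc42ep5 (0.827), Klkb1 (0.79), Gpc3 (0.787), Ccl9 (0.766), Mup10 (0.766), Bcl2l2 (0.714) and Cyp17a1 (0.712). KO_tumor_14M replicate 3 stood apart in Ms4a7 (0.845), Vim (0.754), Tbx19 (0.735) and Cd34 (0.726). The first of these arrays is also 1 of the 3 tumours nearer to the controls on the first principal component. Gpc3 and Tbx19 were flagged at levels below the median of all probe sets (5.03 and 4.44 against 5.196). They were not shown to be above background.

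Camera called 10 lists for the difference of the tumour effect between ages. The tumour effect was higher at 14 months for cell cycle (adjusted p = 5.57e-07), interferon (0.000223) and NRF2 genes (0.00124). It was lower for acute phase (3.38e-05), neutrophil (3.38e-05), T cell (0.000223), cholesterol synthesis (0.00586), inflammation (0.0173), B cell (0.0197) and macrophage genes (0.0336). A lower effect can be a smaller rise. In the same order, the median log2 fold changes against controls at 14 months were -0.269, 0.327, 0.0186, -1.79, 0.133, -0.00352 and 1.13. With an estimated correlation 0 of the 10 lists passed, the smallest adjusted p being 0.83. Evidence for a difference is therefore lacking once the correlation within the lists is estimated, and the cause was not tested.

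Of 10092 probe sets with no gene or several genes, 870 passed the threshold with the ages combined, 278 higher and 592 lower. What they measure was not analysed here.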

How the results depend on the processing

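The alternatives were fixed before the data were examined except for the last 4 named, which were chosen after the result was seen. No named gene or list past the threshold changed direction. Of lists not past it, stellate markers turned in 5 of 22 settings and 7 others in 1 each, and 11 named genes not past it had values on both sides of 0, the widest being Krt19 (-0.24 to 0.47). Repeated quantile normalisation turned the majority of genes at 14 months from higher to lower. The count for tumour vs control, ages combined: genes past the threshold was 6958 over all probe sets, 1443 at an adjusted p under 0.01 and 1224 with at least 2-fold; leaving out each array gave 1814 to 4359. For tumour vs control at 11 months: genes past the threshold numbered 232 with KO_tumor_14M replicates 1 and 2 averaged, 42 at 0.01 and 0 with only the arrays compared; leaving out each array gave 21 to 731. For tumour vs control at 14 months: genes past the threshold numbered 4844 over all probe sets, 5659 with array weights, 657 at 0.01 and 1199 with at least 2-fold; leaving out each array gave 922 to 3537. For tumours at 14 vs 11 months: genes past the threshold numbered 2 over all probe sets, 2 with those tumours averaged, and 0 with array weights, at 0.01 or with only the arrays compared; leaving out each array gave 0 to 4. The difference of the tumour effect between ages and controls at 14 vs 11 months each gave 0 to 1 genes when each array was left out. The value of fold changes at 11 against 14 months went from 0.667 to 0.869 over these omissions. Of gene list tests, 2 passed in camera with an estimated correlation and 22 with fry. Without both nearly identical controls the counts were 1368 with the ages combined, 35 at 11 months, 874 at 14 months, 0 between tumours and 1 between controls. Without control_liver_14M replicate 3 and with those tumours averaged they were 106 at 11 and 754 at 14 months. Only arrays with a number in the title gave 1759 combined, 55 at 11 and 249 at 14 months. Taking the arrays without a number as a block, the counts were 3576 combined, 255 at 11 and 2573 at 14 months, and 5 named genes were lost. Fewer arrays leave less precision, so a lower count is not by itself evidence against a result. The seed match of miR-122 was not run, as no transcripts were given.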

Other observations

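Gene families that stand out were looked for after the results were seen, by Fisher tests over 310 families of gene symbols in each direction, and 6 passed of 620 tests after adjustment. Annexins, which bind membranes in the presence of calcium, were higher in 7 and lower in 0 of 11 (adjusted p = 0.00567), with Anxa2 rising by 3.19, Anxa5 by 2.54 and Anxa1 by 1.65. Toll-like receptors were higher in 6 and lower in 0 of 11 (adjusted p = 0.0373), among them Tlr1 (2.09), Tlr2 (1.58) and Tlr13 (1.47). Genes named after surface antigens (Cd) were higher in 26 and lower in 4 of 89 (adjusted p = 0.000359), including Cd24a (4.27), Cd9 (2.69), Cd44 (2.04) and Cd74 (1.99). Many genes of the last 2 families are made by leukocytes, and the lists of macrophages, with 16 of 28 higher, and neutrophils, with 6 of 17 higher, moved with them (adjusted p = 2.17e-05 and 0.00175, and adjusted p = 0.387 for each with an estimated correlation). The macrophage list itself holds Cd genes such as Cd14 and Cd163, so the 2 are not separate evidence. Cd24a and Cd44 are also on the list of fetal and tumour markers, and the T cell list did not pass (camera adjusted p = 0.0914).

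Of enzyme families, 3 had more members past the threshold lower than by chance. The glucuronosyltransferases (Ugt) had 0 higher and 7 lower of 11 (adjusted p = 0.00567), such as Ugt2b38 (-3.15), Ugt2b1 (-2.76) and Ugt3a1 (-2.58). Hydroxysteroid dehydrogenases (Hsd) had 0 higher and 8 lower of 18 (adjusted p = 0.0233), such as Hsd3b2 (-2.68), Hsd17b2 (-2.22) and Hsd11b1 (-2.06). Aldehyde dehydrogenases had 2 higher and 8 lower of 20 (adjusted p = 0.0373), with Aldh18a1, which makes a proline precursor, rising by 3.04 and Aldh5a1 falling by 1.01. Members of a family can share probes and regulation, so these p-values are too small. Ugt2b38, Ugt2b1 and Hsd3b5 are also on the male-biased list, so the Ugt and Hsd families and that list are not separate evidence.

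All tests of the 3 patterns below were chosen after the result was seen, while the splits of the arrays in the last paragraph were written before.

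The first pattern is that control_liver_11M replicate 1 and control_liver_14M replicate 3 nearly coincide, although they carry different ages. If 1 mouse or 1 RNA were on both, they should share the cluster at every probe set whose arrays form 2 clusters: they did at 16 of 16, which fits, but another pair of tumours, with numbers in their titles, reached 15, so the test is weak (KO_tumor_14M replicates 1 and 2 also shared 16, but their titles end in T and T2 without a number, and whether these are tumours of 1 mouse is not stated). Shared handling of unrelated mice may explain the raised early response genes, 22 of 30 of which stood at least 1 above all other controls in both (Fos 12.68 and 12.73), but the closest other pair of controls shared only 11 of 16. The BioB-3 spike differs by 1.2 between them, against a range of 0.51 over the other 3 controls. The run of each array is not known, so the spike cannot decide on a shared array run. The arrays without a number in the title had the lowest BioB-3 values. These were 7.23 in control_liver_14M replicate 3 and 6.74 and 7.37 in KO_tumor_14M replicates 1 and 2, the others being at 7.61 or above. Whether they are a batch was not tested. Whether the 2 nearly identical controls are 1 animal remains open.

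The second pattern is that KO_tumor_11M replicates 1 and 2 and KO_tumor_14M replicate 4 lie nearer to the controls than the other tumours. If control-like liver had been mixed in, abundant control genes should not lie far below the share that the risen genes imply. Of 1188 such genes, 62 did in KO_tumor_11M replicate 1 (at most 3 in a control array held to the same level). The counts were 31 in KO_tumor_14M replicate 4 (at most 3) and 9 in KO_tumor_11M replicate 2 (at most 5). The control arrays were undiluted while the level was lowered by the share, so their counts may be too low. The 62 and 31 genes speak at most against plain control liver at that share as the sole cause. For KO_tumor_11M replicate 2 it stays open. Liver beside a tumour would be that of a knockout mouse, which was not measured, so the test cannot decide on it. The criterion was revised several times after its values were seen. At the lower share from the fallen genes the counts were 7, 2 and 8, so a smaller share of plain control liver also stays open. Hsd3b5 was at 0.214%, 0.766% and 1.12% of the control level and Slco1a1 at 0.994%, 1.73% and 1.7%, in the same order. These values lie below the lower shares of 8%, 18.7% and 62.2%. The 2 genes were chosen for their fall, so they cannot decide on plain control liver, and male-biased genes kept 48.9% in KO_tumor_11M replicate 2. The Hsd3b5 levels were low (2.885, 4.724 and 5.272, against a median level of all probe sets of 5.196), so its percentages are rough. KO_tumor_11M replicate 2 correlated best with control_liver_11M replicate 1 of the first pattern (r = 0.9751). Some early response genes were high in both (Egr1 12.62 and 13.23, Mt1 13.31 and 12.86), while Fos was at 8.83 and 12.68. Whether handling plays a part was not tested. Age could play a part, but the first component gave an exact permutation p = 0.411 over 56 splits. The time of day, on which the clock gene Dbp depends, was not tested.

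The last pattern is the fall of the male-biased genes. If mice of different sex were compared, Eif2s3y or Xist should differ by many log2 units, but the largest difference of a tumour from the control mean was 1.44, and the lowest Eif2s3y in a tumour was 7.81, so this does not hold. Of 10000 random sets drawn from 226 other hepatocyte genes, 0 had a median as low as -2.88, the lowest being -1.98. These draws take genes as independent, and with an estimated correlation the male-biased list did not pass. The draws therefore cannot decide whether a general fall of hepatocyte genes would be enough. A loss of the hormonal pattern of male liver is also possible, but the cause was not tested.

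Splits of the arrays ask whether any grouping would call as many genes. With the ages combined 1 of 100 drawn splits did, the real one, and at 14 months 1 of 56. For tumours at 14 against 11 months 14 of 56 did, and for the lists 18 of 100 gave as many. The split of the tumours with the most calls put the 3 tumours of the second pattern on one side. It restates their place on the first component and does not show that they are a single group. On the second component KO_tumor_11M replicate 1 and KO_tumor_14M replicate 4 lay at -72.4 and -72.2, but KO_tumor_11M replicate 2 at -25.2. All other arrays lay at 7.93 or above.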
